A study of Rattus norvegicus with 6 samples.

How the data were processed

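RNA immunoprecipitation sequencing (RIP-seq) compares the RNA that comes down with a tagged protein with the RNA of the lysate it was taken from. Per the labels' protocols, ventricular cardiomyocytes were isolated from rats at postnatal days 1 to 2, pre-plated to remove non-myocytes, and transduced with an adenovirus carrying FLAG-tagged MBNL1 for 48 h at a multiplicity of infection of 100. MBNL1 (muscleblind-like 1) is an RNA-binding protein. The cells were lysed and homogenised, the nuclei and debris were pelleted, and 10% of the lysate was kept as Input for each pulldown. The rest was incubated overnight with an anti-FLAG or a control IgG antibody, and the bound RNA was collected on protein A beads. The labels assign 3 libraries to the anti-FLAG pulldown (RIP) and 3 to Input, all from transduced cells. Libraries of the IgG control and of untransduced cells were not analysed here, so the comparison holds no measure of RNA that binds the beads or the antibody alone.

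The deposited table holds raw read counts for 32883 rat genes in the 6 libraries, with no normalization and no summary lines. Per the submitters' processing notes, STAR, featureCounts and DESeq2 were used. Their versions, the genome build, the annotation release, the strand setting and the treatment of multiply mapping reads are not given in the sources used here. Every value reported below was computed from these counts as deposited.

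The table names genes by Ensembl rat gene ID only and does not pair them with symbols. None of the IDs matched the gene table used here, in which 0 of 47357 genes carry an Ensembl ID, so no gene symbol, coordinate, length or GC content is given. The planned tests of 19 gene lists fixed beforehand, the values of MBNL1 and of the estrogen-related receptor genes, the relation to transcript length and GC content, the search for the MBNL binding motif in 3' UTRs, the correction for length and GC, and the normalization without mitochondrial transcripts therefore could not be run. RNA from the adenoviral construct cannot be separated from the endogenous transcript in these counts, and reads shared between near-identical genes could not be checked.

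Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 13823 genes holding at least 99.91% of each library's counts. RIP was compared with Input in edgeR 4.0.16 (R 4.3.3) with TMM factors and the quasi-likelihood F test over all 6 libraries, with no covariate. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. Fold changes are log2 of RIP over Input, and standard errors were taken as the size of the log2 coefficient over the square root of the F statistic. CPM values are relative to the TMM-scaled library unless the library total is named. Comparisons of a single value used a two-sided exact permutation test, for which 3 against 3 libraries allow no p below 0.1. The labels do not say whether the 3 libraries of a group come from separate cultures, so the p-values measure only the spread between these libraries.

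The rule for naming genes was set before the data were examined: the largest changes among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups. With IDs alone, 4 IDs are printed. The most enriched and the 2 most depleted follow that rule without its requirement for a gene symbol. The rule named 5 genes in each direction, and the cut to these was not part of it. The gene with the highest total count was chosen after its values were seen.

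Alternatives set beforehand were DESeq2 1.42.0, limma-voom (limma 3.58.1), edgeR with DESeq2 size factors, with library sizes only and with upper-quartile factors, no filter on low counts, a filter of at least 5 CPM in at least 3 libraries, thinning to the smallest total of 17265349 counts, leaving out each library and each same-numbered pair, and the replicate number as a block. The main test was tested on simulated data with the real genes' means and dispersions. Among 13823 simulated genes it recovered 71.6% of those changed 1.5-fold, 91% of those changed 2-fold and 98.5% of those changed 4-fold, and 3.9% of its calls were false. The simulation changed 67, 67 and 66 genes by these amounts, with as many raised as lowered in all. It held no shift in library composition like that between RIP and Input. Its share of false calls therefore does not carry over to the real comparison, where far more genes passed. No 2 libraries of a group were duplicates: between libraries of one group, the chi-square statistic per degree of freedom over genes with at least 10 counts was 6.88 to 36.05, where sampling noise alone gives about 1. Genes with very high counts weigh heavily in this statistic, so it does not give the spread of a typical gene. The depth was 17265349 to 19325661 counts per library. The median standard error of a log2 fold change was 0.121, which includes both counting error and the spread between libraries. Confidence intervals on shares are 95% Wilson intervals and cover counting error only.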

Results

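The study asked which transcripts are enriched with FLAG-tagged MBNL1 in neonatal rat ventricular cardiomyocytes. It sequenced RNA from 3 anti-FLAG pulldowns (RIP) and 3 Inputs taken from the cleared lysate of transduced cells. The RIP libraries held 17265349 to 18145453 counts and the Input libraries 19150577 to 19325661. A count was seen for 17225 to 17517 genes in RIP and for 17848 to 18059 in Input. On log2(CPM + 1) values across genes, libraries of one group correlated with Pearson's r of 0.993 to 0.995, and RIP with Input libraries with r of 0.929 to 0.942. Genes are not independent replicates, so these correlations are descriptive.

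The RNA recovered with the tagged protein differed from the lysate over most of the transcriptome. Of 13823 genes tested, 4563 (33%) were enriched in RIP and 4824 (34.9%) were depleted (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 4436 did not pass. No overlap between the 3 RIP and the 3 Input values was seen for 71.1% of the tested genes, where chance gives 10%. Most differences were moderate: 75.9% of the tested genes had an estimated change within 2-fold, with quartiles of the log2 fold change at -0.63 and 0.49 around a median of -0.03. The division into enriched and depleted genes depends on the scaling. With TMM, 48.6% of the genes past the threshold were enriched. With library sizes only, the share was 38.2%, and the median log2 fold change was -0.18.

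Large differences were mostly depletions. Among genes past the threshold, 1236 were at least 2-fold higher in RIP and 2085 at least 2-fold lower. With library sizes only these counts were 837 and 2563. At 4-fold or more the counts were 56 enriched and 429 depleted. At 8-fold or more, 91 genes were depleted and 0 were enriched, and the largest enrichment past the threshold was 2.88 on the log2 scale. The count of 8-fold enriched genes was also 0 at an unadjusted p under 0.05 in edgeR and at an adjusted p under 0.05 in DESeq2 and limma-voom, but was 31 in edgeR when genes with low counts were not filtered out. The count of 8-fold depleted genes was then 180. The size limit was applied to estimates after the test of any difference. A test against the 2-fold limit itself (edgeR's glmTreat, chosen after seeing the data) called 634 genes higher and 1150 lower.

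**Figure D1:**
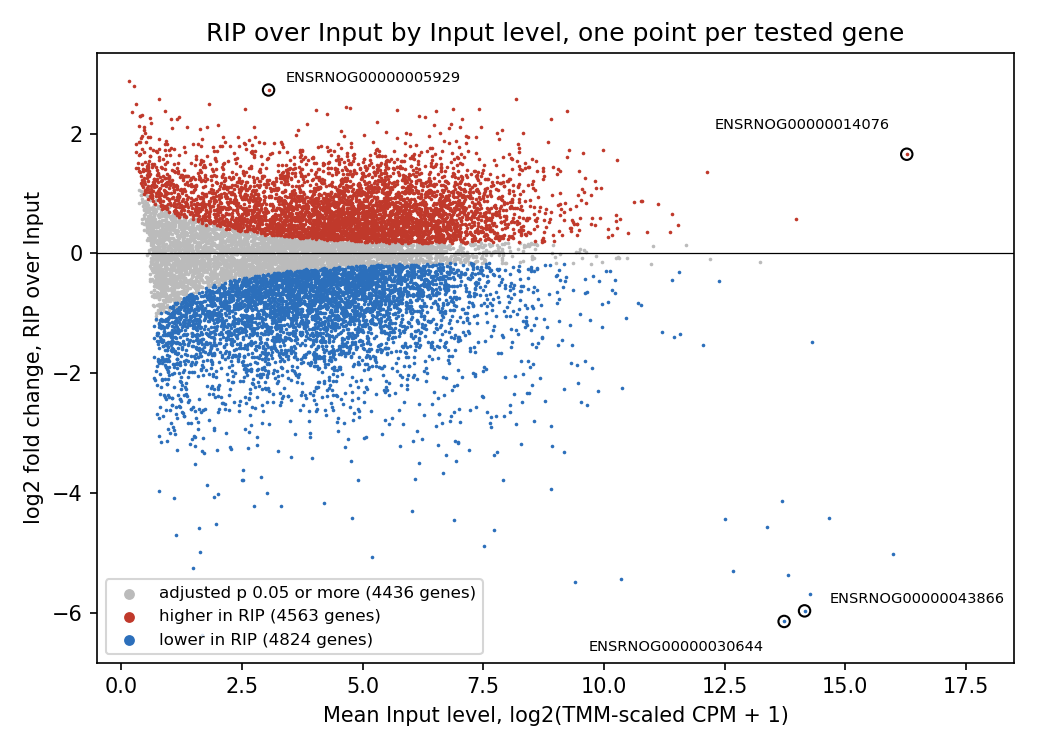
Log2 fold change of RIP over Input (vertical axis) against the mean Input level as log2 of TMM-scaled CPM plus 1 (horizontal axis), with 1 point for each of the 13823 tested genes. Red points are the 4563 genes enriched and blue points the 4824 depleted at an adjusted p under 0.05, gray points did not pass, and circles mark the 4 genes whose IDs are given in the text.

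One gene, ENSRNOG00000014076, held the highest count in every library. It took 23.49% ± 4.3 (SD, n = 3) of the counts in RIP and 8.348% ± 0.553 (SD, n = 3) in Input. Its share was 28.09% (95% Wilson interval 28.07 to 28.11), 22.8% (22.78 to 22.82) and 19.58% (19.56 to 19.6) in RIP replicates 1, 2 and 3. In Input replicates 1, 2 and 3 it was 8.89% (8.88 to 8.91), 8.36% (8.35 to 8.38) and 7.79% (7.78 to 7.8). All 3 RIP shares lay above all 3 Input shares (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows). In the test across genes its log2 fold change was 1.66 (SE 0.15, edgeR adjusted p = 2.17e-09), a 3.15-fold enrichment. It ranked 178 among enriched genes by fold. Without gene symbols it could not be checked whether its counts include RNA from the adenoviral construct, which all the cells received. Its share is therefore not shown to be that of an endogenous transcript.

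The most enriched gene by the rule set beforehand was ENSRNOG00000005929. It rose from 7.29 ± 0.467 CPM in Input to 48.4 ± 4.87 CPM in RIP (SD, n = 3 each), a log2 fold change of 2.73 (SE 0.11, edgeR adjusted p = 2.46e-15). This rested on 138 to 166 counts per Input library and 769 to 879 per RIP library.

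The 2 most depleted genes were among the most abundant in the lysate. ENSRNOG00000030644 fell from 13600 ± 2520 CPM in Input to 192 ± 38.1 CPM in RIP (SD, n = 3 each), with a log2 fold change of -6.15 (SE 0.17, edgeR adjusted p = 9.51e-18). ENSRNOG00000043866 fell from 18300 ± 1650 to 291 ± 55.6 CPM (SD, n = 3 each), with a log2 fold change of -5.97 (SE 0.14, edgeR adjusted p = 1.79e-18). Neither rests on low counts, since the RIP libraries held 2458 to 3891 and 4471 to 5568 counts of them.

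The transcripts that dominate the lysate were mostly depleted. Of the 20 tested genes with the highest Input level, 14 were depleted, 3 were enriched and 3 did not pass. Of these 20 genes, 10 were depleted at least 8-fold, by 17.6-fold to 70.9-fold. These 10 genes held 20.3% ± 2.3 of the counts in Input and 0.58% ± 0.09 in RIP (SD, n = 3 each). The most abundant Input gene after ENSRNOG00000014076 fell from 6.796% ± 0.885 of the counts to 0.1895% ± 0.017 (SD, n = 3 each). The count of 14 depleted genes among these 20 was the same in DESeq2 and in edgeR with each of the other scalings. Of the genes ranked 21 to 100 by Input level, 36 were enriched and 30 depleted, which turned to 31 and 36 with library sizes only. Of those ranked 101 to 1000, 498 were enriched and 272 depleted, and with library sizes only 411 and 304. Of those ranked 1001 to 5000, 1791 were enriched and 1410 depleted, which turned to 1347 and 1635 with library sizes only. Below rank 5000, 2235 genes were enriched, 3098 were depleted and 3490 did not pass, and with library sizes only 1666 were enriched and 3601 depleted.

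All 91 genes depleted at least 8-fold together held 20.97% ± 2.32 of the counts in Input and 0.6202% ± 0.0922 in RIP (SD, n = 3 each). The 91 genes were chosen on these same libraries. Most of both shares lay in the 10 abundant genes above, which held 20.3% ± 2.3 and 0.58% ± 0.09 (SD, n = 3 each). Genes were also chosen without a pair of same-numbered libraries and measured in that pair. Leaving out pairs 1, 2 and 3 gave 118, 112 and 97 genes, of which 85, 86 and 74 were among the 91. In Input 1, 2 and 3 these sets held 22.8%, 18.3% and 21.9% of the counts. In RIP 1, 2 and 3 they held 0.63%, 0.54% and 0.72%. Such summed shares do not show how the less abundant genes of each set fared.

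**Figure D2:**
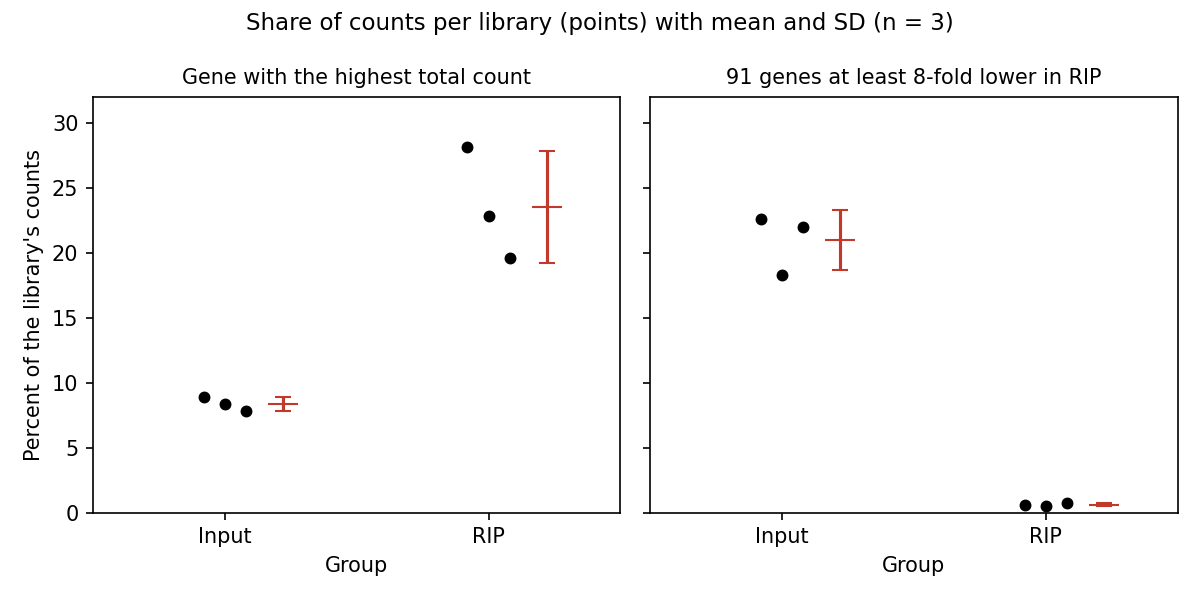
Percent of each library's counts (vertical axis) taken by ENSRNOG00000014076, the gene with the highest total count (left), and by the 91 genes at least 8-fold lower in RIP (right), for Input and RIP. Points are the 3 libraries of a group and the red marks are the mean and SD; the left share is higher in every RIP library (19.58% or more) than in every Input library (8.89% or less), and the right share is 18.31% or more in Input and 0.72% or less in RIP.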

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

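No gene past the threshold in the main fit was past it in the opposite direction under any of 19 alternative fits, of which the one with the leading gene left out of the library sizes and TMM was chosen after seeing the data. Such a reversal was unlikely from the start, because the fits share libraries and their median log2 fold change ranged only from -0.18 to -0.003. Of the main calls tested again, 85.9% (without replicate pair 2) to 99.9% (leading gene left out) stayed past the threshold in the same direction. Under the 19 fits 3458 to 4711 genes were enriched and 3933 to 5590 depleted, and the 4 printed IDs kept their direction and stayed past the threshold. Leaving out a library or a same-numbered pair gave 4010 to 4428 enriched and 4190 to 4748 depleted genes. At 2-fold or more these ranges were 1200 to 1311 and 2008 to 2222, but library sizes only gave 837 and 2563, and the filter of at least 5 CPM, which tests fewer genes, gave 835 and 1426. Library sizes alone lowered the enriched share of called genes from 48.6% to 38.2% and the median log2 fold change to -0.18, since they do not correct for the composition of the libraries. Testing against the 2-fold limit itself, added after seeing the data, called fewer genes, 634 enriched and 1150 depleted, because it asks for a change beyond that limit. Without the filter on low counts, 180 genes in place of 91 were depleted at least 8-fold; the cause was not tested. With the replicate block, 4616 genes were enriched and 4877 depleted. Deviations of same-numbered RIP and Input libraries from their group means correlated at 0.055, 0.182 and 0.065. Every library correlated best with its own number, a hint from the data that the numbers mark a shared lysate, which the labels do not state. The planned corrections for length and GC and the normalization without mitochondrial transcripts were not run, for lack of gene annotation. Thinning all libraries to the smallest total gave 4554 enriched and 4776 depleted genes. The smallest change past the threshold was 0.17 on the log2 scale.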

Other observations

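The tests on the strongly depleted genes, on carry-over and on the sign of the relation to abundance were chosen after the results were seen, and that on sample splits was set out before. The fold change was weakly related to the level in the lysate. With the level taken from 1 Input library and the fold change fitted without that library, Spearman's rho across genes was 0.112, 0.116 and 0.108 for Input 1, 2 and 3, and 0.11 with all Input libraries in both. Genes are not independent replicates. The 10% of genes with the highest Input level had a median log2 fold change of 0.24 to 0.28. It was -0.15 to -0.11 in the 10% just below the middle level and -0.01 to 0 in the lowest 10%, so it did not rise steadily among the tested genes. The lowest 10% had a median Input level of only 0.679 to 0.776 CPM. Genes with so few Input counts can pass the count filter through their RIP libraries alone, which favors higher fold changes there. The median of the lowest 10% is therefore not read as a feature of the RNA. A scaling factor per library leaves the gaps between these median fold changes as they are. In the highest 10%, 51.5% to 53.5% of the genes were enriched and 30.1% to 31.3% depleted with TMM factors. Noise of the Input libraries enters the Input level and the fold change with opposite signs. It can only lower rho, so it does not account for the value of 0.11. The fits without an Input library kept the same-numbered RIP library. If these share a lysate, noise common to both could raise rho in those fits, so their values are not free of shared noise. Transcript length and GC content stay open, as neither could be measured.

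The fold changes reached further down than up. Relative to the median log2 fold change, the 1st percentile lay at -2.68 and the 99th at 1.75, distances that do not change with a scaling factor per library. Without the filter on low counts they lay at -3.64 and 2.88. The leading gene takes up counts that would otherwise go to all others, which could lower them. From its shares, the most that this can move every other gene between a RIP and an Input library is -0.36 on the log2 scale, too little to account for genes at least 8-fold lower in RIP. Their identity, and whether they share a cell compartment that the tagged protein or the lysis does not reach, could not be tested without gene names. Of the 10 such genes among the 20 most abundant in Input, 9 had their lowest Input level in replicate 2.

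Moderate fold changes over most genes could arise if a RIP library held mostly lysate RNA that was carried over in proportion. In that case no gene would fall below 0.5 of its Input level in CPM of the library total. Of 9762 genes of at least 5 CPM, 1024 had every RIP library below 0.5 of every Input library, which argues against it. The lowest ratio of RIP to Input, 1.27% (0.996% to 1.5% over the RIP libraries), bounds the share of a RIP library that such carry-over could make up, if the carried RNA had the composition of Input. Background that prefers some transcripts stays open, because no control IgG library was analysed here.

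The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 9387 genes, and 1 of the 10 splits, the real one, reached that number. The highest count among the other 9 was 0 in edgeR, with at most 70 genes at an unadjusted p under 0.05, and 1 gene in DESeq2, against 8893 genes for the real split in DESeq2. Each of the other 9 splits put RIP and Input libraries in both groups. The difference between RIP and Input then widened the spread within groups, so counts near 0 were bound to follow. No conclusion on chance is drawn from them.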
